A study of Pimephales promelas with 51 samples.

How the data were processed

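RNA was taken from pooled homogenates of whole fathead minnow larvae and made into QuantSeq 3′ libraries with unique molecular identifiers, per the labels' protocols. The submitters' processing notes name bcl2fastq 2.20.0, STAR 2.7.10a, HTSeq 2.0.1, FastQC, MultiQC 1.12 and edgeR, without saying what each was used for. The genome build and whether molecular identifiers were used to remove duplicates are not given in the sources used here. Intervals and tests therefore cover counted reads.

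The authors deposited a table of counts per gene for each compound, with 36695 genes and HTSeq's rows for unassigned reads, and the DMSO columns of both were identical. They also deposited log2 tables, which were checked here and equal log2 of TMM-normalised CPM plus 1 after edgeR's expression filter, with 18075 and 17877 genes and differences within a tolerance of 1e-06. The counts were used for every test. Rows for unassigned reads stayed out of library sizes and tests. Reads assigned to no counted feature were 22.6 to 33.6% of all reads per library, and are called reads outside genes below. Where those reads lie was not examined, so some may lie within genes. A further 10.6 to 12.2% aligned to several places, 6.94 to 8.77% were unaligned and 0.59 to 0.80% ambiguous. No sample column was left unused.

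Genes were filtered with filterByExpr (minimum count 10, minimum total 15), normalised by TMM and tested with edgeR 4.0.16 (quasi-likelihood F-test, robust) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each compound's 24 libraries and the 3 DMSO libraries formed 1 fit of 9 groups. Trends used log10 nominal concentration in the 24 treated libraries. Direct comparisons used all 51 libraries, at the highest concentrations and at 3 pairs with measured concentrations within 1.25 times of each other. Of 17174 LOC-numbered genes, 8751 matched a gene number in the reference table of assembly fPimPro1.hap1.1, which was used only for names, and 2292 took a symbol from it. No coordinates are given.

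The 23 gene lists were written before the data were examined, and 664 of their 827 entries matched a gene. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, and again with an estimated correlation. The median, mean and camera direction of a list differed in sign for heat shock and skin genes with dexamethasone, and for complement, exocrine pancreas and ionocytes with fluticasone propionate, none of them called. Lists with under 5 measured members were not tested. No list covers gut, kidney, heart, vessels or notochord, and some genes are in more than 1 list. The target score was fitted with a Hill curve of slope 1 per compound and 1000 residual bootstrap draws. A plateau was taken as reached where the upper 95% bound of the half-maximal concentration lay within the tested range. Benchmark concentrations came from Hill curves on nominal concentration, leaving out genes outside the tested range.

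Named genes were fixed by rule: the 10 largest rises and falls at each highest concentration with an adjusted p under 0.05, at least 5 CPM in the higher group and all treated libraries beyond all DMSO libraries; all measured receptor targets; the 5 smallest p in each direction per trend; up to 5 per direction in each direct comparison; and up to 4 per other list. From this pool the text gives examples, and some genes the rule names are not reported. Genes without a symbol were skipped. These were 3 among the rises and 2 among the falls for dexamethasone at 25 µM, and 1 and 2 for fluticasone propionate at 0.19 µM. In the trends 5 were skipped among the falls for dexamethasone and 2 for fluticasone propionate. For dexamethasone 0.08 µM against fluticasone propionate 0.19 µM, 3 were skipped among genes higher in dexamethasone and 2 among those lower.

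Replicates were checked for duplicates. The chi-square per degree of freedom between the 51 pairs within groups was 1.47 to 3.14, above sampling noise. On simulated counts with 200 changed genes, the fit for dexamethasone 25 µM against DMSO recovered 52% of genes changed by 1 and 88.8% of those changed by 2 on the log2 scale, with 4 false among 142 calls. For fluticasone propionate 0.19 µM these were 43.8% and 90.6%. The dexamethasone trend had 12 false among 180 calls and the fluticasone propionate trend 4 among 101. At the highest concentrations, dexamethasone against fluticasone propionate had 9 false among 142, and labels 0.08 against 0.19 µM 3 among 142. Changes of 0.3 per log10 unit of concentration were recovered for 73.2% of genes in the dexamethasone trend and 33% in the other. Simulated genes varied independently of each other. The simulated benchmark concentrations were estimated at a median of 1.06 times the true value for dexamethasone and 1.35 times for fluticasone propionate, whose tested range is narrower. DESeq2 1.42.0, other normalisation, filters, libraries, a replicate block and leaving out each library were tried as alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.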

Results

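Whole larvae of the fathead minnow, a small freshwater fish used in toxicity testing, were exposed for 24 h to dexamethasone or to fluticasone propionate, and gene expression was measured by sequencing the 3′ ends of messenger RNA. Both compounds are synthetic fluorinated corticosteroids that activate the glucocorticoid receptor. Fluticasone propionate differs from dexamethasone in carrying a propionate ester and a fluoromethyl thioester group. The data comprised 51 libraries in 17 groups of 3: DMSO, 8 concentrations of dexamethasone and 8 of fluticasone propionate. Groups are named by their labelled concentration. The measured concentration of dexamethasone was 0.0066 µM in the lowest group and 23.6726 µM in the highest, and that of fluticasone propionate was 0.0019 µM and 0.0597 µM. Reads assigned to genes numbered between 1316614 and 2097358 per library, with a median of 1618729. The labels describe RNA from pooled homogenates and do not say how the replicates of a group were kept apart, so p-values measure the spread between these libraries. All fold changes are on the log2 scale with their standard error, with 3 libraries per group, and adjusted p-values are from edgeR's quasi-likelihood test unless another method is named.

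The first comparison asked which genes responded to dexamethasone. At 25 µM the largest rises included fkbp5, a co-chaperone of steroid receptors, which went from 130 ± 25.0 CPM (SD, n = 3) in DMSO to 635.3 ± 15.8 CPM, a log2 fold change of 2.29 ± 0.20. The stress-induced mTOR inhibitor ddit4 rose by 1.71 ± 0.26 and lpin1a, of the lipin phosphatidate phosphatases, by 1.61 ± 0.26. Rises of 1.71 ± 0.38 for pfkfb4b, which encodes an enzyme controlling glycolytic flux, and 1.51 ± 0.17 for rps6kb1a, an S6 kinase, were also called. The other genes with the largest rises were si:dkey-5i3.5 (2.06), entpd2b (1.96), tmem88bl (1.83), mgarpb (1.72) and mat2ab (1.66). Glutamine synthetase, glulb, rose by 1.1 ± 0.11. The largest falls included genes used in DNA replication and division: tk1 (-2.28), chek1 (-2.13), cdk2 (-1.97), the centromere gene cenpx (-2.39) and the nuclear importin kpna2 (-2.01). Large falls were also those of si:dkey-9l20.3 (-3.99 ± 0.92), zgc:86764 (-2.0) and the carbonic anhydrase ca4b (-1.89). Values at 25 µM were as low as 0.68 ± 1.18 CPM for si:dkey-9l20.3, 1.22 ± 0.50 for cenpx and 1.54 ± 1.36 for tk1 (SD, n = 3). The sizes of these falls are therefore uncertain. In all, 239 of 18075 genes were called at 25 µM, 123 higher and 116 lower than DMSO, with 107 without replicate B of DMSO and 410 in a fit of only the 6 compared libraries.

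Of the 24 measured members of the list of glucocorticoid receptor targets, 6 rose at 25 µM dexamethasone, none fell and 18 were not called, and 7 rose when adjusted over the list alone. Those called were fkbp5, ddit4, klf9 (0.99 ± 0.20), tsc22d3 (0.68 ± 0.13), cebpd (0.59 ± 0.12) and zbtb16a (0.55 ± 0.13). Values for other members were 0.11 ± 0.19 for sgk1, 0.06 ± 0.22 for per1a, 0.001 ± 0.13 for per1b and -0.51 ± 0.26 for nfkbiaa, none of them called. The list as a set was higher (limma camera, adjusted p = 2.38e-07, and adjusted p = 0.00856 with an estimated correlation). Its entry lpin1 matched no tested gene under that symbol, so lpin1a, named above, was not treated as a member.

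Of the 38 measured cell cycle genes, 9 fell at 25 µM and 29 were not called, and 24 fell when adjusted over the list alone. The replication clamp pcna fell by 1.40 on the log2 scale, from 123.4 to 46.97 CPM, the proliferation marker mki67 fell by 1.24 and the spindle gene tpx2 fell by 1.40. The set was lower (camera adjusted p = 3.15e-24, and adjusted p = 0.0067 with an estimated correlation). Among 17 xenobiotic metabolism genes 3 fell: cyp3a65, a drug-metabolising cytochrome (-1.35 ± 0.16), gstp1, a glutathione transferase (-0.94 ± 0.17), and abcc2, an efflux transporter (-0.73 ± 0.15). That set was lower (camera adjusted p = 0.00748, and adjusted p = 0.0451 with an estimated correlation), but not without replicate A of the 25 µM group (adjusted p = 0.0977). The 15 myeloid markers were lower as a set (camera adjusted p = 0.0013, and adjusted p = 0.0374 with an estimated correlation) with none called singly. Among 39 matrix genes, 3 fell, the type I collagen genes col1a2 (-0.52 ± 0.10), col1a1b (-0.45 ± 0.10) and col1a1a (-0.43 ± 0.11). The matrix set was lower at camera adjusted p = 8.18e-05, with adjusted p = 0.141 with an estimated correlation. The gluconeogenesis and amino acid catabolism set was higher at camera adjusted p = 8.68e-05, with adjusted p = 0.141 with an estimated correlation, and 1 of its 39 members was called, the carboxykinase pck2 (0.69 ± 0.15). The muscle proteolysis and autophagy set was higher at camera adjusted p = 0.0132, with adjusted p = 0.391 with an estimated correlation, and its called members were glulb and glula (0.58 ± 0.14), which encode glutamine synthetases and not proteases. That set did not pass without replicate B of the 25 µM group (camera adjusted p = 0.064) or A of DMSO (0.103).

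The other lists did not pass the set test at 25 µM dexamethasone. Their camera adjusted p-values were 0.0582 for circadian clock, 0.119 for oestrogen and androgen responsive genes, 0.139 for inflammation, 0.181 for complement and coagulation, 0.251 for interferon response, 0.421 for neural and retina markers, 0.425 for both erythroid and exocrine pancreas markers, 0.456 for both lipid metabolism and the stress axis, 0.76 for both ionocytes and liver markers, 0.791 for skeletal muscle, 0.836 for lymphoid markers, and 0.906 for both heat shock genes and skin markers. Circadian clock passed without replicate A of the 25 µM group (0.0384) or A of DMSO (0.0414), and inflammation without replicate A of the 25 µM group (0.0273). Some members were called singly. The clock genes tefb (0.73 ± 0.13) and npas2 (0.61 ± 0.16) rose, as did the ammonium transporter rhcga (1.04 ± 0.25), the complement gene c7b (0.65 ± 0.15) and the cholesterol transporter abca1a (0.63 ± 0.16). Photoreceptor genes rcvrn2 (-0.76 ± 0.13), opn1sw2 (-0.69 ± 0.12) and opn1sw1 (-1.05 ± 0.25) fell, as did the glial fatty acid binding gene fabp7a (-0.63 ± 0.17), the pancreatic carboxypeptidase cpa1 (-0.69 ± 0.14), the apolipoprotein apom (-0.90 ± 0.13), the bile acid binding protein fabp6 (-0.72 ± 0.13), the fatty acid transporter cd36 (-0.74 ± 0.17) and agr2 (-1.06 ± 0.24).

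At lower concentrations of dexamethasone the number of called genes did not follow the concentration. It was 35 at 8 µM, 24 at 2.5 µM, 447 at 0.8 µM and 3 at 0.25 µM. Leaving out 1 library at a time it was 12 to 28 at 8 µM, 0 to 29 at 2.5 µM (0 without replicate C of the group or A of DMSO) and 0 to 30 at 0.25 µM (30 without replicate C of the group, 0 without any other). A fit of only the 6 compared libraries gave 149, 404 and 302 at 8, 2.5 and 0.25 µM. Without the filter on low counts these were 144, 144 and 131. A fit with replicate letter as a block called more genes than the main fit at 8, 2.5, 0.8 and 0.25 µM. At 0.8 µM, 206 genes were higher and 241 lower. In that group the share of reads outside genes, those assigned to no counted feature, averaged 30.4 ± 2.8% (SD, n = 3), against 25.0 ± 0.5% in DMSO. With that share as a covariate the count at 0.8 µM was 4, without replicate A of the group it was 32, and without that and the other 5 dexamethasone libraries above 30% it was 190. At 25 µM the share was 25.8 ± 1.3%, and the count was 358 with the covariate. No gene was called at 0.08, 0.025 or 0.008 µM by edgeR or by DESeq2. There 1052, 1254 and 624 of 18075 genes had an unadjusted p under 0.05, and 2, 4 and 2 were called without the filter. The receptor target fkbp5 had log2 fold changes of 0.28 ± 0.20 at 0.8 µM, 1.15 ± 0.20 at 2.5 µM and 1.71 ± 0.20 at 8 µM, of which the last 2 were called. At lower concentrations it lay below DMSO without being called, at -0.59 ± 0.22 at 0.25 µM, -0.55 ± 0.22 at 0.08 µM, -0.21 ± 0.21 at 0.025 µM and -0.12 ± 0.21 at 0.008 µM. The count of called genes by concentration is plotted for both compounds.

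**Figure D1:**
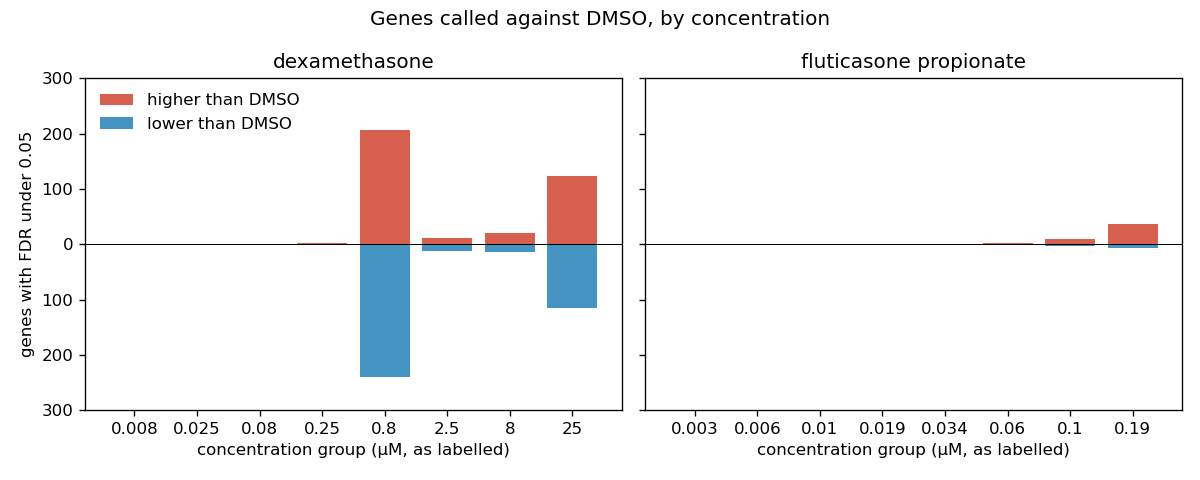
Genes with an adjusted p under 0.05 against DMSO (vertical axis, higher above and lower below 0) in each labelled concentration group (µM) of dexamethasone and fluticasone propionate. Dexamethasone 0.8 µM stands at 206 higher and 241 lower genes, and fluticasone propionate 0.19 µM at 37 and 7.

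The second comparison asked the same of fluticasone propionate. At 0.19 µM fkbp5 rose by 1.5 ± 0.25, from 127.4 ± 24.2 to 360.5 ± 35.7 CPM (SD, n = 3), and glulb by 1.0 ± 0.10, from 387.4 to 776.7 CPM. Further rises were those of mgarpb (1.36 ± 0.19), rps6kb1a (1.2 ± 0.14), the polycomb gene cbx7a (1.28 ± 0.29), the muscle ankyrin repeat gene ankrd1b (1.2 ± 0.27), the cytochrome cyp27c1 (1.09 ± 0.22) and the kinase gene sgk2b (1.06 ± 0.24). The genes si:ch211-217a12.1 (1.29) and si:dkey-5i3.5 (1.24) rose too. The named falls were those of ahsg1 (-0.73 ± 0.17), cyp3a65 (-0.70 ± 0.13), fabp6 (-0.62 ± 0.12), gstp1 (-0.59 ± 0.11) and hmgb1a (-0.43 ± 0.10). In all 44 of 17877 genes were called, 37 higher and 7 lower. The count was 17 without replicate C of the 0.19 µM group, 17 without replicate B of DMSO, 78 with the share of reads outside genes as a covariate, 126 without the filter on low counts and 129 with only the 6 compared libraries.

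Among the receptor targets 1 of 24 rose at 0.19 µM fluticasone propionate, fkbp5, and 23 were not called, with the same count of 1 adjusted over the list alone. Uncalled values were 0.65 ± 0.24 for klf9, 0.64 ± 0.44 for ddit4, 0.35 ± 0.17 for cebpd and 0.30 ± 0.13 for tsc22d3. The set was higher at camera adjusted p = 0.00158, with adjusted p = 0.107 with an estimated correlation. The cell cycle set was lower at camera adjusted p = 1.91e-09, with adjusted p = 0.194 with an estimated correlation. None of its 37 members was called, 8 fell when adjusted over the list alone, and pcna had -0.59 ± 0.30 and mki67 -0.73 ± 0.25. The interferon response set was lower (camera adjusted p = 0.00158, and adjusted p = 0.0256 with an estimated correlation). None of its 13 members was called, and 2 were lower when adjusted over the list alone. Values were -1.27 ± 0.36 for irf9 and -1.32 ± 0.45 for irf1b. At 0.19 µM these genes had only 5.76 ± 1.48 and 5.55 ± 3.47 CPM (SD, n = 3), so the sizes are uncertain. The clock genes tefb (0.67 ± 0.13) and npas2 (0.73 ± 0.16) rose.

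Other sets passed only with the preset correlation of 0.01 at 0.19 µM. Circadian clock (camera adjusted p = 0.0309), muscle proteolysis (0.0187), gluconeogenesis (0.00399) and heat shock genes (0.0484) were higher, and matrix genes (0.012) and liver markers (0.0291) were lower, each with adjusted p = 0.22 with an estimated correlation. The xenobiotic set was lower at camera adjusted p = 0.03, with adjusted p = 0.107 with an estimated correlation. Each of these 7 sets lost its call when at least 1 single library was left out, with camera adjusted p-values of up to 0.114 for circadian clock, 0.147 for muscle proteolysis, 0.0755 for gluconeogenesis, 0.211 for heat shock genes, 0.137 for matrix genes, 0.126 for liver markers and 0.168 for the xenobiotic set. The lists that did not pass had camera adjusted p-values of 0.228 for myeloid markers, 0.255 for lipid metabolism, 0.266 for erythroid markers, 0.56 for both neural markers and the stress axis, 0.677 for inflammation, lymphoid markers and oestrogen and androgen responsive genes, 0.828 for ionocytes, skeletal muscle and skin markers, 0.874 for exocrine pancreas and 0.875 for complement.

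**Figure D2:**
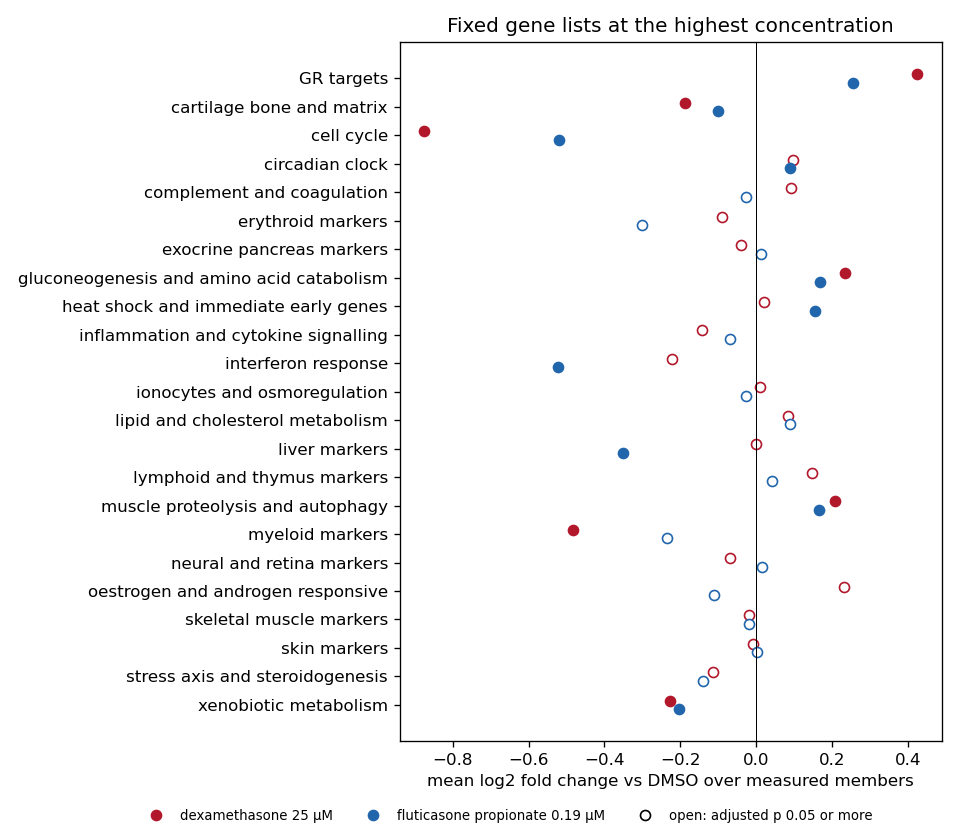
Mean log2 fold change against DMSO (horizontal axis) over the measured members of each fixed gene list, for dexamethasone 25 µM and fluticasone propionate 0.19 µM, with open points where the camera adjusted p was 0.05 or more. Cell cycle genes lie lowest for dexamethasone and receptor targets highest.

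At 0.1 µM fluticasone propionate 13 genes were called and at 0.06 µM 3, which included glulb (0.55 ± 0.10) and rps6kb1a (0.71 ± 0.14). Leaving out 1 library at a time gave 4 to 11 at 0.1 µM (4 without replicate C of the group) and 0 to 3 at 0.06 µM (0 without replicate B of DMSO). With only the 6 compared libraries the counts were 43 and 7, and without the filter 50 and 14. At 0.003 µM 1 gene was called by edgeR and none by DESeq2. No gene was called by edgeR or DESeq2 at 0.006, 0.01, 0.019 or 0.034 µM, where 659, 627, 1278 and 1021 of 17877 genes had an unadjusted p under 0.05. Without the filter 8, 7, 20 and 18 genes were called there, and at 0.019 µM 20 without replicate A of the group.

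The third comparison asked which genes followed the concentration among treated libraries alone, with no use of DMSO. The slopes are log2 changes per log10 unit of concentration. For dexamethasone 387 genes were called, 233 rising and 154 falling. The rising genes with the smallest p were glulb (0.33 ± 0.03), mgarpb (0.49 ± 0.05), the lysophospholipase gene enpp2l (0.26 ± 0.03), the lipid droplet gene pnpla3 (0.35 ± 0.04) and tmem88bl (0.66 ± 0.08). The falling ones, with 5 genes without a symbol passed over, were rcvrn2 (-0.22 ± 0.03), cyp3a65 (-0.35 ± 0.04), apom (-0.22 ± 0.03), ugdh (-0.20 ± 0.04) and pcna (-0.32 ± 0.05). For fluticasone propionate 279 genes were called, 197 rising and 82 falling. The leading rises were glulb (0.55 ± 0.05), rps6kb1a (0.69 ± 0.07), enpp2l (0.47 ± 0.06), the muscle gene xirp2a (0.39 ± 0.05) and mgarpb (0.65 ± 0.09). The leading falls, with 2 genes without a symbol passed over, were gstp1 (-0.39 ± 0.05), fabp6 (-0.34 ± 0.05), ces3 (-0.51 ± 0.09), apom (-0.30 ± 0.05) and zgc:136930 (-0.61 ± 0.10). Without the highest concentration the counts were 80 and 33. Without all libraries of 1 replicate letter they were 126 to 304 for dexamethasone and 92 to 120 for fluticasone propionate, and with the share of reads outside genes as a covariate 420 for fluticasone propionate.

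**Figure D3:**
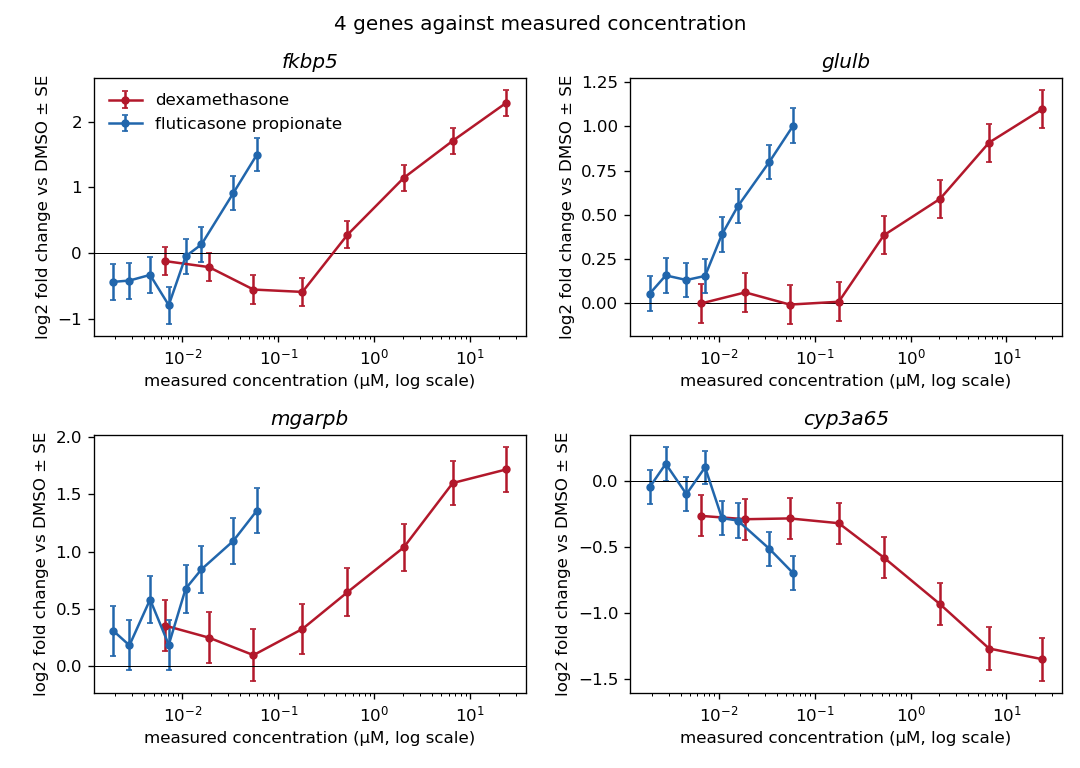
Log2 fold change against DMSO with its standard error (vertical axis) of fkbp5, glulb, mgarpb and cyp3a65 by measured concentration (µM, log axis) of each compound. At the highest concentration fkbp5 reaches 2.29 for dexamethasone and 1.5 for fluticasone propionate.

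The compounds were then compared with each other. Between 25 µM dexamethasone and 0.19 µM fluticasone propionate, whose concentrations differ, edgeR and DESeq2 each called no gene. Of 18606 tested genes 982 had an unadjusted p under 0.05, near the share that chance gives. A fit without the filter on low counts called 18, and a fit of only these 6 libraries 9. The difference, dexamethasone minus fluticasone propionate, was 0.79 for fkbp5 (95% interval 0.35 to 1.22), 0.09 for glulb (-0.12 to 0.30), 1.07 for ddit4 (0.39 to 1.75) and -0.65 for cyp3a65 (-0.99 to -0.31), with intervals not adjusted for the number of genes. The target list was higher in dexamethasone (mean difference 0.17, camera adjusted p = 0.0235, and adjusted p = 0.18 with an estimated correlation).

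At matched measured concentrations, 0.055 µM dexamethasone (label 0.08 µM) against 0.0597 µM fluticasone propionate (label 0.19 µM), 64 genes were called, 10 higher and 54 lower in dexamethasone. Those lower in dexamethasone included fkbp5 (-2.06 ± 0.24), glulb (-1.02 ± 0.10), the creatine transporter slc6a8 (-0.93 ± 0.14), mgarpb (-1.26 ± 0.20) and tasor2 (-1.26 ± 0.20). Those higher included dnah2, of the dynein heavy chains (1.04 ± 0.22), capn9, a calpain (0.90 ± 0.21), cep112 (1.13 ± 0.26), poc1a (3.13 ± 0.74) and ces3 (0.77 ± 0.19). The size for poc1a is uncertain, as it had 0.54 ± 0.93 CPM (SD, n = 3) in the fluticasone propionate group. The receptor target list was lower in dexamethasone, with a mean difference, dexamethasone minus fluticasone propionate, of -0.32 (camera adjusted p = 4.22e-05, and adjusted p = 0.0429 with an estimated correlation). The groups also differed by 4.83 percentage points in the share of reads outside genes. With that share as a covariate 63 genes were called, only 34 of them among the 64. The count was 30 without libraries above 30%, 29 without replicate C of the fluticasone propionate group and 237 without the filter on low counts. At the lower matched pairs, labels 0.008 against 0.019 µM and 0.025 against 0.06 µM, no gene was called by edgeR or DESeq2. Of 18606 tested genes 1013 and 812 had an unadjusted p under 0.05, and without the filter 26 and 11 were called. In the first of these pairs the target list was higher in dexamethasone (mean difference 0.20, camera adjusted p = 0.00678, and adjusted p = 0.287 with an estimated correlation). Against the DMSO mean, the list averaged 0.008 in that dexamethasone group and -0.206 in that fluticasone propionate group. The difference therefore lay in fluticasone propionate values below DMSO, not in a rise with dexamethasone. In the second pair the target list was not called (mean difference 0.054, camera adjusted p = 0.791, and adjusted p = 0.935 with an estimated correlation).

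The score of the target list, the mean log2 CPM of its members minus the DMSO mean, was 0.41 ± 0.06 (SD, n = 3) at 25 µM dexamethasone, 0.19 ± 0.12 at 8 µM and 0.07 ± 0.08 at 2.5 µM. For fluticasone propionate it was 0.25 ± 0.06 at 0.19 µM, 0.14 ± 0.08 at 0.1 µM and -0.21 ± 0.09 at 0.019 µM. The DMSO libraries had an SD of 0.065. Neither curve reached a plateau within the tested range, so no half-maximal concentration or potency ratio is given.

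**Figure D4:**
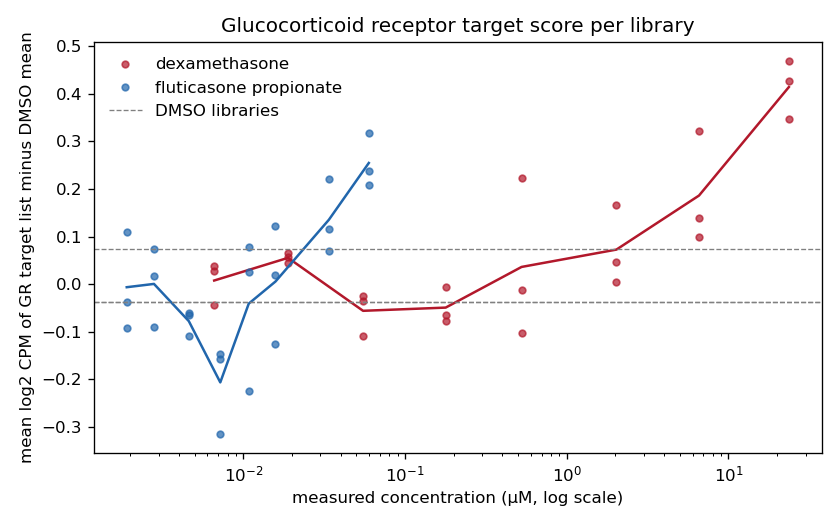
Score of the receptor target list per library (vertical axis, log2) by measured concentration (µM, log axis), with lines through group means and dashed lines at the 3 DMSO libraries. The highest group means are 0.41 for dexamethasone and 0.25 for fluticasone propionate.

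Genes called in the trend tests had a median benchmark concentration, where the fitted curve had moved by 1 residual SD, of 0.924 µM nominal for dexamethasone (386 genes) and 0.0397 µM nominal for fluticasone propionate (279 genes). The 10th percentiles were 0.144 and 0.0147 µM, with 0.0919 µM for dexamethasone without replicate C for the same genes. On measured concentration the fluticasone propionate median was 0.0124 µM, and the 10th percentiles were 0.0943 and 0.00507 µM. For a move of 2 SD the medians were 4.08 and 0.112 µM nominal and the 10th percentiles 0.747 and 0.0437 µM. The tested nominal range was 0.008 to 25.5 µM for dexamethasone and 0.00344 to 0.191 µM for fluticasone propionate. Benchmarks outside it were left out. As the ranges differ between the compounds, these values cannot be read as a potency ratio.

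The responses to the compounds overlapped. Of the rising trend genes 86 were shared, against 2.63 for independent lists, and of the falling ones 41 against 0.71, with no gene going opposite ways. The slopes, which share no controls, had a correlation of 0.38 across 17449 genes, which are not independent replicates. At the highest concentrations 29 called rises and 5 called falls were shared, against 0.26 and 0.05 for independent lists. The fold changes there correlated at 0.59, against 0.50 on average in 20 simulations with no effect and simulated DMSO libraries shared by both compounds. Their covariance was 0.076 against 0.052 simulated. Genes in the simulations varied independently of each other, so patterns that move many genes together in real libraries are missing from them. The excess over the simulated values therefore cannot by itself be read as a shared response. Those simulations called at most 2 genes per direction, so they give no overlap of calls to set beside the observed one. With no DMSO library in common, 2 for 1 compound and the third for the other in all 6 ways, 3 to 9 called rises and 0 to 1 called falls were shared, against at most 0.025 and 0.007 for independent lists. The fold changes then correlated at 0.091 to 0.1653. These fits have fewer controls and take the spread of a lone DMSO library from the other groups, and part of the overlap with all 3 may come from the shared controls.

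**Figure D5:**
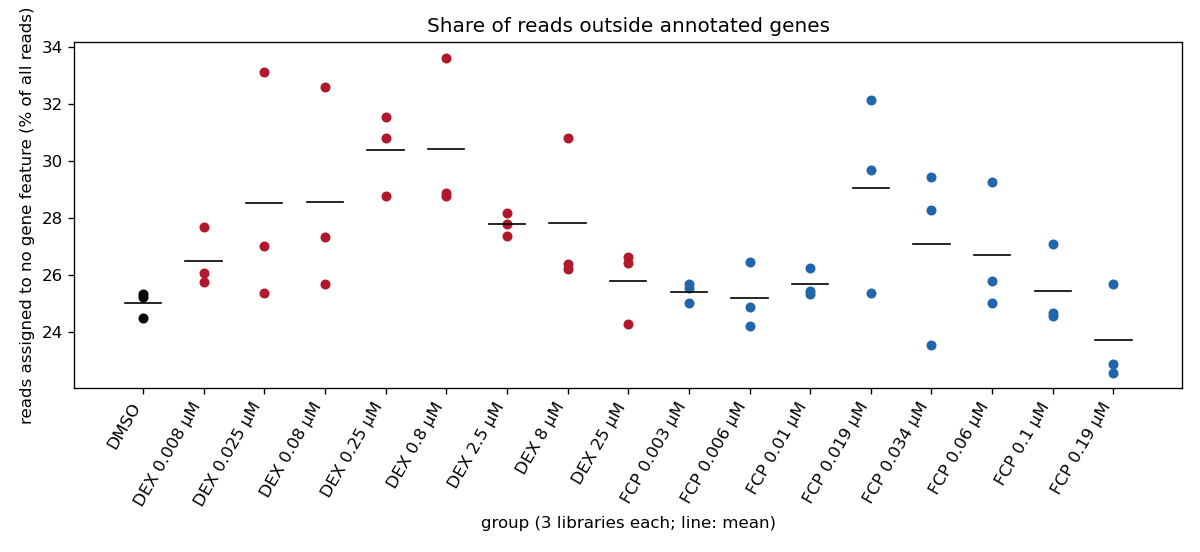
Percent of all reads assigned to no gene feature in each library (points) with the group mean (line), for DMSO and each concentration (µM) of both compounds. DMSO averages 25.0% and dexamethasone 0.8 µM 30.4%.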

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

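The tests of each explanation were written down before their values were seen, but the fits with the share of reads outside genes as a covariate, those without libraries above 30%, and the test of that share by replicate letter were chosen after the data were seen, and the differences of fkbp5 and glulb between the compounds were known before the target list was compared.

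The share of reads outside genes, which was used only in alternatives and in tests of explanations, was above the highest DMSO library (25.3%) in every library of 9 treated groups. The group means were 26.5%, 28.5%, 28.6%, 30.4%, 30.4%, 27.8% and 27.8% for dexamethasone 0.008, 0.025, 0.08, 0.25, 0.8, 2.5 and 8 µM, and 25.7% and 29.1% for fluticasone propionate 0.01 and 0.019 µM. It also went with the replicate letter: A had the highest share of its group in 7 of 8 dexamethasone groups (mean deviation of 2.105 percentage points for A, permutation p = 0.005, adjusted p = 0.01 over the 2 compounds) and the lowest in 6 of 8 fluticasone propionate groups (-1.478 points, permutation p = 0.02, adjusted p = 0.02), with 100000 permutations of the letters within groups. The labels do not say what the letters stand for and name no batch.

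Dexamethasone at 0.8 µM had 447 called genes, more than any higher concentration. A larger glucocorticoid response is argued against by the target score, which differed by -0.378 from that at 25 µM. Library composition that follows the share of reads outside genes may account for part of the count: slopes estimated within fluticasone propionate groups predicted the sign of 94.2% of the called genes, with a predicted size of 0.431 times the measured one. The count also depends on single libraries. It was 32 without replicate A, which had the highest share in this group. Without that and the other 5 dexamethasone libraries above 30% it was 190. It was 50 without replicate B of DMSO, 95 without replicate A of DMSO and 168 without replicate C of DMSO. It rose to 578 without replicate B of the 0.8 µM group. It was also larger without the filter on low counts and with replicate letter as a block. A response peculiar to this concentration stays open and was not tested.

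Cell cycle genes were lower at the highest concentration of both compounds, although the call for fluticasone propionate is lost with an estimated correlation (adjusted p = 0.194). The share of reads outside genes predicted a median change of 0.039 for the list at fluticasone propionate 0.19 µM, where -0.62 was measured, which argues against it. DMSO libraries standing apart are argued against by the median slope among dexamethasone libraries without DMSO, -0.216 per log10 unit of concentration (camera on the slope with the preset correlation, p = 5.36e-23). Lower proliferation under both compounds may be the reason, as may a difference in the stage or number of larvae per pool, and neither was tested.

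At matched measured concentrations 64 genes differed between dexamethasone 0.08 µM and fluticasone propionate 0.19 µM by a direct test. The log2 differences, dexamethasone minus fluticasone propionate, were 1.04 for dnah2, 0.90 for capn9, 1.13 for cep112, 3.13 for poc1a, 0.77 for ces3, -1.02 for glulb, -2.06 for fkbp5, -0.93 for slc6a8, -1.26 for mgarpb and -1.26 for tasor2. A larger glucocorticoid response to fluticasone propionate may be 1 source, since the mean difference of the target list was -0.315, although part of it lies in the dexamethasone group, where fkbp5 (-0.554 ± 0.215) and klf9 (-0.688 ± 0.231) lay below DMSO without being called. Library composition may be another: its slopes predicted the sign of 78.1% of the 64 genes with a size of 0.147 times the measured one. But 54 of the 64 were lower in dexamethasone, and predicting that direction for all would do at least as well. The share of signs therefore cannot decide the question. With the covariate 63 genes were called, 34 of them among the 64, so both stay open.

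Splits of 3 libraries against 3 number 10, too few for a share under 0.05. In them the real count and the highest of the other splits were 3 and 0 for dexamethasone 0.25 µM, 447 and 0 for 0.8 µM, 24 and 0 for 2.5 µM, 35 and 0 for 8 µM, and 239 and 0 for 25 µM. For fluticasone propionate they were 1 and 0 at 0.003 µM, 0 and 2 at 0.006 µM, 3 and 0 at 0.06 µM, 13 and 0 at 0.1 µM, and 44 and 1 at 0.19 µM. They were 64 and 6 for dexamethasone 0.08 µM against fluticasone propionate 0.19 µM, 0 and 1 for 0.008 against 0.019 µM, and 0 and 0 in every other comparison of groups. For the trends 1 of 100 orders of the libraries, the real one, gave as many genes for either compound. The counts were 387 against 95 at most for dexamethasone and 279 against 34 for fluticasone propionate. The other orders moved libraries singly, so they cannot tell a trend with concentration from differences shared by the 3 libraries of a group.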

How the results depend on the processing

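The fits with the share of reads outside genes as a covariate, those without libraries above 30% of such reads, those with the DMSO libraries divided between the compounds, and the check of the replicate letters within each compound were chosen after the data were seen, and the other alternatives before. With 3 libraries per group and a median of 1618729 reads in genes, simulated changes of 1 on the log2 scale were recovered for 52% of genes at dexamethasone 25 µM, so counts of called genes leave out many changes of that size. Of 3770 values of named genes under the alternatives, 3457 kept their side of the threshold, 171 were no longer called, 69 became called, 73 changed sign while not called, and no called value reversed. Values uncalled both in the main fit and under the alternative count among those kept. The share kept therefore does not give the stability of called genes alone. Where no cause is given below, the cause was not tested.

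Without the filter on low counts, called genes numbered 2, 4, 2, 131, 703, 144 and 144 for dexamethasone 0.008, 0.025, 0.08, 0.25, 0.8, 2.5 and 8 µM, and 7, 8, 7, 20, 18, 14, 50 and 126 for fluticasone propionate from 0.003 to 0.19 µM. They numbered 18 for dexamethasone 25 µM against fluticasone propionate 0.19 µM, 26 for 0.008 against 0.019 µM, 11 for 0.025 against 0.06 µM and 237 for 0.08 against 0.19 µM. DESeq2 gave 22 at dexamethasone 0.25 µM, 46 at 2.5 µM and 0 at fluticasone propionate 0.003 µM. With only the 6 compared libraries, there were 302, 404, 149 and 410 for dexamethasone 0.25, 2.5, 8 and 25 µM, 5, 5, 5, 7, 43 and 129 for fluticasone propionate 0.003, 0.019, 0.034, 0.06, 0.1 and 0.19 µM, 9 for dexamethasone 25 against fluticasone propionate 0.19 µM and 4 for 0.008 against 0.019 µM. With all 51 libraries in the fit, dexamethasone 0.25 µM had 6.

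With the share of reads outside genes as a covariate, called genes numbered 0, 4 and 60 for dexamethasone 0.25, 0.8 and 8 µM, 1 and 78 for fluticasone propionate 0.06 and 0.19 µM, and 420 for the fluticasone propionate trend. Without libraries above 30% they numbered 0, 190 and 119 for dexamethasone 0.25, 0.8 and 2.5 µM, and 30 for dexamethasone 0.08 against fluticasone propionate 0.19 µM. Without the highest concentration the trends had 80 and 33, with fewer libraries and a narrower range.

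The labels do not say that a replicate letter pairs libraries. Within each compound libraries of the same letter deviated together a little: the mean correlation of residuals was 0.041 for the same letter and -0.02 for others with dexamethasone, and 0.019 and -0.01 with fluticasone propionate. It was over 0.1 for 15 and 5 of 84 same-letter pairs. With 3 letters, 16 and 15 of 24 libraries correlated best with their own letter, more than an even spread over the letters would give. The letter was left out of the main fits because the labels state no pairing, and an effect of it is not excluded. Over all 51 libraries the means were 0.007 and -0.003, values that pool the compounds although their deviations in the share of reads outside genes go opposite ways. A fit with replicate letter as a block gave 69, 847, 80 and 99 for dexamethasone 0.25, 0.8, 2.5 and 8 µM and 1 for fluticasone propionate 0.034 µM.

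With the DMSO libraries divided, the called rises shared at the highest concentrations numbered 3 with B and C for dexamethasone and A for fluticasone propionate, 7 the other way round, 6 with A and C against B, 9 the other way round, 3 with A and B against C and 7 the other way round, where 29 were shared with all 3. The shared falls numbered 1, 0, 1, 0, 0 and 1 in that order, where 5 were shared. A lone DMSO library was assumed to vary as much as the libraries of the other groups.

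With an estimated correlation the camera adjusted p was 0.141 for the matrix and gluconeogenesis lists and 0.391 for muscle proteolysis with dexamethasone. With fluticasone propionate it was 0.194 for cell cycle, 0.107 for receptor targets and xenobiotic metabolism, and 0.22 for the matrix, circadian, gluconeogenesis, heat shock, liver and muscle proteolysis lists. With a prior count of 0.5 heat shock genes had 0.0602. The receptor target score at dexamethasone 25 µM was 0.332 without fkbp5. The median and 10th percentile of the benchmark concentration moved to 4.08 and 0.747 µM for dexamethasone and 0.112 and 0.0437 µM for fluticasone propionate at 2 SD, a larger change by construction. On measured concentration the 10th percentile was 0.0943 µM for dexamethasone, and the median and 10th percentile were 0.0124 and 0.00507 µM for fluticasone propionate, whose measured values lie below nominal ones.

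Leaving out 1 library at a time, the counts ranged from 107 to 199 for dexamethasone 25 µM (107, 154 and 158 without DMSO B, DMSO A and the group's B), 12 to 28 for 8 µM (12 and 20 without DMSO A and B), 0 to 29 for 2.5 µM (0 without its C or DMSO A, 3 without DMSO B, 4 and 7 without its B and A) and 32 to 578 for 0.8 µM (32 without its A, and 50, 95 and 168 without DMSO B, A and C). At 0.25 µM the range was 0 to 30, with 30 without its C and 0 without any other library, and at 0.08, 0.025 and 0.008 µM 0 to 0. For fluticasone propionate they were 17 to 38 at 0.19 µM (17 without its C or DMSO B, 18 without DMSO A, 28 without its B), 4 to 11 at 0.1 µM (4 and 8 without its C and A, 5 and 6 without DMSO B and A), 0 to 3 at 0.06 µM (0 without DMSO B, 1 without its A or C), 0 to 20 at 0.019 µM (20 without its A), 0 to 1 at 0.003 µM (0 without its A, its B, DMSO A or DMSO C) and 0 to 0 at 0.006, 0.01 and 0.034 µM. The trends, without all libraries of 1 replicate letter, had 126 to 304 (126 and 132 without B and C) and 92 to 120 (92, 93 and 120 without A, B and C). Dexamethasone 0.08 against fluticasone propionate 0.19 µM had 29 to 62 (29 without the latter's C, 30 without the former's A), 0.008 against 0.019 µM 0 to 3 (1 without the former's A, 3 without the latter's A), 0.025 against 0.06 µM 0 to 1 (1 without the former's C) and 25 against 0.19 µM 0 to 0.

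The camera adjusted p for dexamethasone ranged, leaving out 1 library at a time, from 2.85e-25 to 4.11e-17 for cell cycle, 7.54e-08 to 1.42e-05 for receptor targets, 4.84e-06 to 0.00267 for matrix, 3.43e-05 to 0.00818 for gluconeogenesis, 0.000275 to 0.0146 for myeloid, 0.00324 to 0.0977 for xenobiotic (0.0977 without the group's A) and 0.00324 to 0.103 for muscle proteolysis (0.064 without the group's B, 0.103 without DMSO A). It ranged from 0.0384 to 0.174 for circadian clock (0.0384 without the group's A, 0.0414 without DMSO A), 0.0273 to 0.547 for inflammation (0.0273 without the group's A), 0.0807 to 0.657 for complement, 0.339 to 0.751 for erythroid, 0.117 to 0.919 for pancreas, 0.83 to 0.937 for heat shock, 0.0977 to 0.417 for interferon, 0.448 to 0.936 for ionocytes, 0.264 to 0.85 for lipid, 0.417 to 0.849 for liver, 0.534 to 0.849 for lymphoid, 0.125 to 0.919 for neural, 0.0515 to 0.333 for oestrogen and androgen, 0.402 to 0.919 for skeletal muscle, 0.424 to 0.846 for skin and 0.359 to 0.672 for the stress axis.

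For fluticasone propionate it ranged from 1.57e-11 to 0.000146 for cell cycle, 0.00118 to 0.0172 for receptor targets and 0.000798 to 0.0411 for interferon. It crossed 0.05 for matrix (0.00263 to 0.137; 0.137 without the group's B, 0.0678 without DMSO C), gluconeogenesis (0.00184 to 0.0755; 0.0755 without the group's B, 0.0594 without DMSO B), muscle proteolysis (0.00452 to 0.147; 0.147 without DMSO A, 0.0755 and 0.0732 without the group's B and C), liver (0.0104 to 0.126; 0.126 and 0.0853 without the group's B and C, 0.0989 and 0.0507 without DMSO A and C), xenobiotic (0.0118 to 0.168; 0.168 and 0.0594 without DMSO A and B, 0.116 without the group's C) and circadian clock (0.0259 to 0.114; 0.0612, 0.0671 and 0.0783 without the group's A, B and C, 0.114 and 0.0523 without DMSO B and C), and heat shock genes did not pass whichever of the 6 libraries was left out (0.0741 to 0.211). The others were 0.422 to 0.94 for complement, 0.137 to 0.707 for erythroid, 0.0928 to 0.789 for pancreas, 0.353 to 0.976 for inflammation, 0.338 to 0.94 for ionocytes, 0.126 to 0.542 for lipid, 0.542 to 0.863 for lymphoid, 0.0709 to 0.695 for myeloid, 0.0837 to 0.94 for neural, 0.341 to 0.963 for oestrogen and androgen, 0.683 to 0.965 for skeletal muscle, 0.259 to 0.879 for skin and 0.311 to 0.733 for the stress axis.

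The receptor target score ranged, without 1 replicate letter, from 0.39 to 0.428 for dexamethasone 25 µM and 0.205 to 0.30 for fluticasone propionate 0.19 µM. The median benchmark concentration was 0.802 to 0.974 and 0.0359 to 0.039 µM, and the 10th percentile 0.0919 to 0.145 µM for dexamethasone (0.0919 without replicate C) and 0.0107 to 0.0134 µM for fluticasone propionate. For these benchmarks only the curves were refitted. The genes stayed those called in the trend tests on all libraries, so the ranges leave out changes in the calls. No receptor target curve reached a plateau under any alternative run.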

Other observations

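No test in this part was chosen before the data were seen. The first principal component of the 51 libraries held 8.91% of the variance and followed the share of reads outside genes (Pearson r = -0.957, Spearman rho = -0.936, two-sided permutation p = 1e-05 for each, the smallest that 100000 permutations can give, and 2e-05 adjusted over the 2 components). The correlation was -0.945 without the 2 libraries farthest from the median share, -0.965 within dexamethasone libraries and -0.921 within fluticasone propionate libraries. Among the 8 libraries of 1 replicate letter it was between -0.969 and -0.744 for dexamethasone and between -0.934 and -0.796 for fluticasone propionate. The second component held 4.85% of the variance, with r = -0.237 (permutation p = 0.1) and rho = -0.131 (p = 0.4), and r was -0.35 within dexamethasone libraries and -0.43 within fluticasone propionate libraries.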
